A study of Mus musculus with 28 samples.

How the data were processed

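RNA from the dorsal hippocampus of male C57Bl6 mice was profiled in 28 libraries of 6 groups. Per the labels, hippocampi were dissected and snap-frozen, total RNA was extracted with a NucleoSpin RNA kit, mRNA was enriched, and stranded libraries were read from both ends on a DNBseq instrument. The submitters' processing notes name FastQC, MultiQC, HTSeq 0.6.1 and the genome build mm10, and the aligner and the annotation release are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, made by the authors with HTSeq, with 5 summary rows at the end that name no gene. The table was checked for whole numbers, for unequal library totals and for a column per sample, and 0 columns lacked a sample. Every pair of libraries within a group differed by more than counting noise, with the lowest chi-square per degree of freedom at 5.94, so that no library was a copy of another of its group.

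The table holds 50686 genes, of which 310 had no symbol and 50376 had a position in the GENCODE M21 annotation of GRCm38 (mm10), the source of the coordinates given here. Totals over genes ranged from 16.2 to 20.3 M counts per library (M, 10 to the power of 6). The filterByExpr function of edgeR, with a minimum count of 10 and a minimum total of 15, left 16735 genes, which held 99.9% of the gene counts in the lowest library. Levels are in CPM, counts scaled to a library total of 10 to the power of 6, on library sizes adjusted by the trimmed mean of M values (TMM), and log2 CPM used a prior count of 2. At this depth and with 4 or 5 libraries per group, the spread between libraries limited precision more than counting did for genes with high counts. For genes with few counts, counting noise weighed more. The common biological coefficient of variation was 0.133. Intervals and p-values of single genes and of scores measure the spread between these libraries, since the labels do not say whether each came from a separate mouse. The camera test compares the genes of a list with other genes, so its p-values at a preset correlation also rest on the spread across genes.

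Groups followed the conditioning and treatment labels: Basal (no conditioning, no treatment, n = 4), Vehicle (n = 4), Cort, RU486, C108 and C118 (n = 5 each), the latter 5 after auditory fear conditioning. Vehicle was compared with Basal, each ligand with Vehicle, and the 4 ligands with each other in 6 direct comparisons. All 11 comparisons came from a single quasi-likelihood fit of edgeR 4.0.16 (robust, 22 residual degrees of freedom) to all 28 libraries in R 4.3.3. Tests were two-sided, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Counts at an unadjusted p under 0.05 are also given, where chance alone gives a share of 0.05 of the 16735 tested genes. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of the quasi-likelihood F statistic. No paired analysis was possible because the sample numbers in the titles are unique, so that groups share no number to pair libraries on.

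The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those that passed with a mean of at least 1 CPM (5 and 5 between ligands). It also named up to 4 members with the smallest p from each list with a called member or a called list test, and the 5 genes with the smallest unadjusted p where fewer than 5 passed. Nr3c1, Nr3c2, Fkbp5, Sgk1, Tsc22d3, Per1, Fos, Arc, Npas4 and Ttr were always named in comparisons with Vehicle or Basal. Of the named genes, those with the clearest bearing on a comparison are given. Results for some genes are not reported here. There were 30 fixed lists of marker and pathway genes, each with at least 5 tested members. They included glucocorticoid receptor target genes, immediate early genes, circadian clock genes, and markers of neural, vascular, meningeal and blood cells and of the regions next to the hippocampus.

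Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 30 lists within a comparison. The calls were repeated with the correlation between genes estimated from the data, and with fry, which tests whether a list's genes move one way without comparing them with other genes. For each list, members were also counted after adjustment over all genes and adjusted over the list alone. A list's score in a library is the mean log2 CPM of its members after centring each gene on all 28 libraries. Scores of the glucocorticoid receptor targets were compared between groups by exact permutation tests, with 95% intervals from inverting the test, and this test was chosen after the data were seen. Covariance across genes of the ligand effects was compared with 20 simulations of all 28 libraries without group effects. There genes were drawn independently, and the ligand groups shared simulated Vehicle libraries. It was also computed for the 6 ways to divide the real Vehicle libraries 2 and 2.

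Alternatives were DESeq2 1.42.0 (Wald test), limma-voom with sample quality weights, relative log expression (RLE) normalization, no filter on low counts, a mean of at least 5 CPM, only the 2 groups compared, and leaving out each library in turn. The sample number, the choroid plexus score and 1 surrogate variable from sva 3.50.0 were each tried as a covariate. Added after the data were seen were fits without Vehicle libraries 16 and 29, fits without C118 libraries 20 and 38, and fits with the thalamus and neocortex scores as covariates. Up to 100 splits of the libraries of each comparison, the real one included, were fitted in the same way. Scores, intervals and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the main results.

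The tests were tried on simulated data with the depths, abundances and dispersions of these libraries. For Vehicle against Basal, edgeR recovered 56.9% of genes changed 1.5-fold, 69.7% of those changed 2-fold and 86.2% of those changed 3-fold, and called 10 of 16392 unchanged genes. For C108 against Vehicle it recovered 61.2%, 79.1% and 90.8%, with 3 false calls, and for Cort against RU486 49.3%, 83.3% and 90.8%, with 4 false calls. Of 20 unchanged lists per comparison, camera called 0 with either correlation, while fry called 1 in Cort against RU486. Genes were simulated independently of each other and the lists were random. Correlation between genes and uneven tissue in the real libraries were not reproduced, so these rates of false calls need not hold there.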

Results

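Gene expression was measured in 28 libraries of dorsal hippocampus from male C57Bl6 mice. The Basal mice (n = 4) had neither conditioning nor treatment. All others underwent auditory fear conditioning, a task in which a tone is paired with a shock, and received vehicle (n = 4) or a ligand of the glucocorticoid receptor (GR). The ligands were Cort (n = 5), which is the usual abbreviation of corticosterone, the main glucocorticoid of mice, and RU486 (mifepristone, n = 5), an antagonist of the glucocorticoid and progesterone receptors. The remaining ligands, C108 (n = 5) and C118 (n = 5), are known here by code names alone. Doses and times are not given in the sources used here. Gene counts per library, in M (10 to the power of 6), totalled 18.53 to 20.06 in Basal, 18.62 to 19.14 in Vehicle, 19.02 to 20.03 in Cort, 16.24 to 19.6 in RU486, 18.62 to 20.15 in C108 and 17.33 to 20.3 in C118.

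Vehicle against Basal shows what conditioning together with vehicle handling changed, and the design does not separate them. Target genes of the glucocorticoid receptor rose in the conditioned mice. Fkbp5, a cochaperone of the receptor (chromosome 17, 28399094 to 28517527, GRCm38), went from 67.5 ± 9.53 CPM (SD, n = 4) to 130 ± 13 CPM (SD, n = 4), a log2 fold change of 0.95 ± 0.10 (SE, adjusted p = 1.8e-06). Tsc22d3, which encodes the anti-inflammatory protein GILZ (chromosome X, 140539528 to 140600659), rose from 45.7 ± 11.9 to 121 ± 19.2 CPM (SD, n = 4 each, edgeR adjusted p = 1.29e-05). Cdkn1a, the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 7.43 ± 2.88 to 44.4 ± 5.72 CPM (SD, n = 4 each, edgeR adjusted p = 4.39e-05). The receptor gene itself, Nr3c1 (chromosome 18, 39410545 to 39519421), fell to 82.7 ± 3.78 CPM (SD, n = 4), a log2 fold change of -0.51 ± 0.09 (SE, adjusted p = 0.00135).

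Of the 37 tested members of the receptor target list, 24 rose and 1 fell over all genes, and 29 rose and 1 fell adjusted over the list alone. Their median log2 fold change was 0.86, and the list was called by camera (adjusted p = 4.82e-46) and with an estimated correlation (adjusted p = 0.000284). The largest rises among the members included Plin4, a coat protein of lipid droplets, at 3.65 ± 0.37 (SE, log2), and Hif3a, a hypoxia-inducible transcription factor, at 2.45 ± 0.31 (SE, log2). Sgk1, a kinase that regulates ion channels, rose by 1.11 ± 0.24 (SE, log2, adjusted p = 0.00615). With only the 2 groups in the fit that call was lost (adjusted p = 0.149), and Basal 9 stood at 130 CPM with the next Basal library at 58.3. The mineralocorticoid receptor gene Nr3c2 fell by 0.50 on the log2 scale (adjusted p = 0.0379). That call was lost on leaving out 6 of the 8 libraries in turn, with adjusted p-values from 0.0628 (Basal 9) through 0.08 (Basal 14), 0.0839 (Basal 1), 0.0884 (Basal 27) and 0.127 (Vehicle 16) to 0.152 (Vehicle 29).

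**Figure D1:**
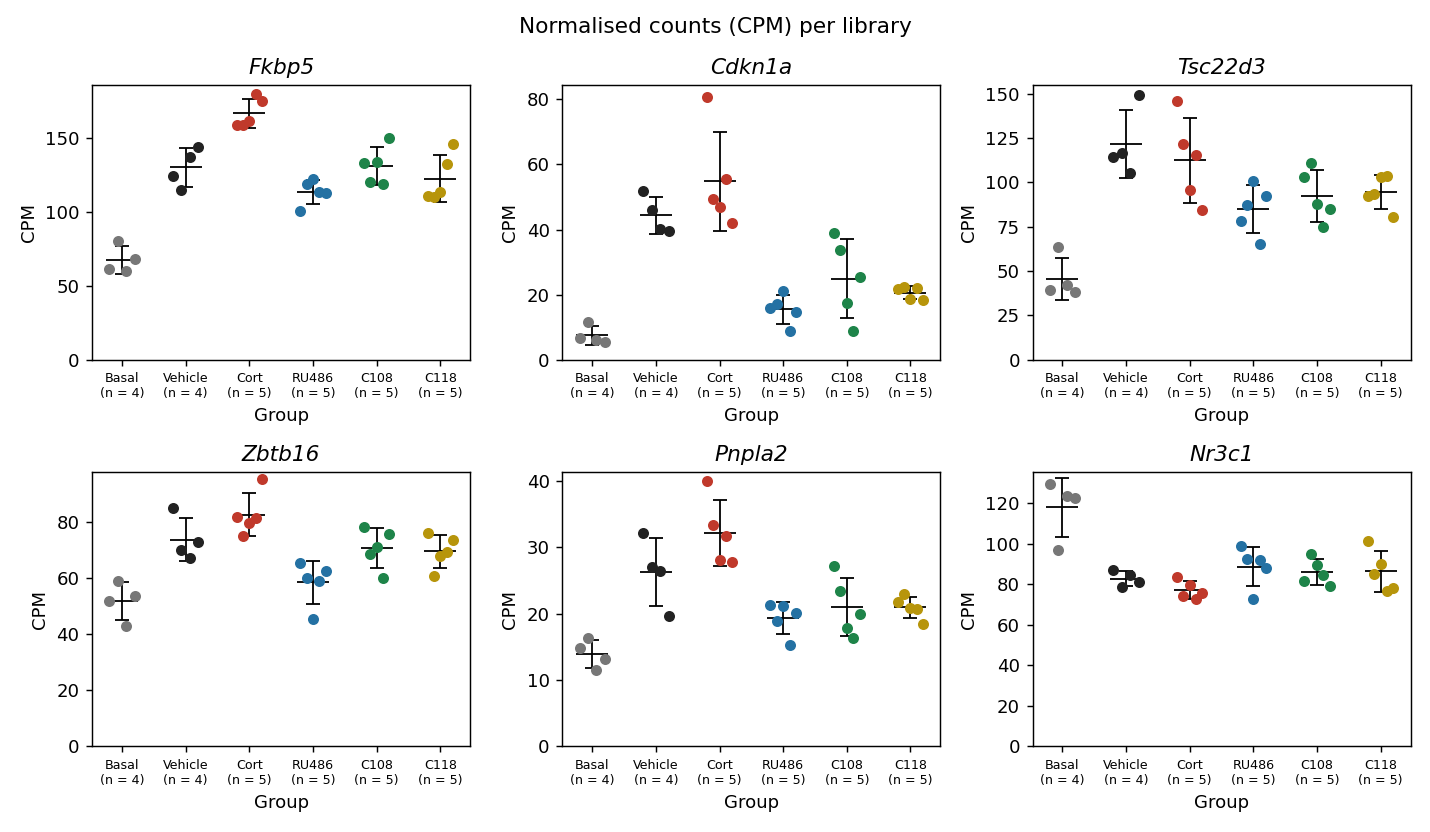
Normalised counts (CPM, vertical axis, from 0) of Fkbp5, Cdkn1a, Tsc22d3, Zbtb16, Pnpla2 and Nr3c1 in each library of the 6 groups, with bars for the mean ± SD. Fkbp5 averaged 67.5 CPM in Basal, 130 in Vehicle and 167 in Cort, and Cdkn1a averaged 54.9 CPM in Cort against 15.5 in RU486.

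Among the other genes with the largest rises were Ada, an adenosine deaminase, at 2.88 ± 0.38 (SE, log2), Etnppl, an astrocyte enzyme of phospholipid metabolism, at 1.91 ± 0.31, and Xdh, xanthine dehydrogenase, at 1.88 ± 0.34. Lcn2, a secreted iron-siderophore carrier, went from 0.0241 ± 0.0482 to 0.895 ± 0.426 CPM (SD, n = 4 each). The largest falls included Insc, a spindle orientation factor, at -1.98 ± 0.26, Erbb3, a neuregulin receptor, at -1.91 ± 0.25, and Wnt9a at -1.85 ± 0.31 (SE, log2), whose call was lost with only the 2 groups in the fit (adjusted p = 0.0822). Kdr, the main receptor of vascular endothelial growth factor, fell by 1.59 and Pdgfrb, the pericyte receptor of platelet-derived growth factor, fell by 0.88 on the log2 scale. Of 14 pericyte markers 1 fell over all genes and 1 adjusted over the list alone (median -0.34, camera adjusted p = 0.0118), a call that was lost, with adjusted p = 0.796 with an estimated correlation. Of 23 endothelial markers 1 rose and 1 fell, and the list was not called (adjusted p = 0.13). Of 40 immediate early genes, Tiparp and Gadd45g rose and Nr4a3 and Dusp6 fell, and the list was not called (median -0.08, adjusted p = 0.669). The call of Gadd45g was lost without Basal 1 (adjusted p = 0.136), Basal 14 (0.112), Basal 27 (0.125), Vehicle 3 (0.117), Vehicle 23 (0.0709) or Vehicle 29 (0.0583) and with no filter (0.0785). That of Dusp6 was lost without Basal 1 (adjusted p = 0.104), Basal 14 (0.153), Basal 27 (0.115), Vehicle 3 (0.0784), Vehicle 16 (0.0753) or Vehicle 29 (0.132) and with no filter (0.115), and that of Nr4a3 without both Vehicle 16 and 29 (0.0995). Fos had 5.36 ± 1.32 CPM against 5.79 ± 2.65, Arc 70.5 ± 19.6 against 92.0 ± 8.56 and Npas4 2.91 ± 1.03 against 4.01 ± 1.22 CPM (SD, n = 4 each), and none of the 3 passed. Among activity-regulated genes of the later wave, 1 rose and 4 fell, with the potassium channel genes Kcna4 (-1.02) and Kcnj4 (-0.61) among the falls. Its list call (adjusted p = 0.044) was lost, with adjusted p = 0.796 with an estimated correlation.

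Markers of cell types and regions were tested as lists. Over all genes, 2 of 22 astrocyte markers rose, 4 of 24 myelin genes, 4 of 17 dentate gyrus markers and 3 of 14 CA1 markers fell, and 0 of 13 mitochondrially encoded genes passed. Thalamus markers had a median log2 fold change of 0.91, with 1 of 15 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000725). With an estimated correlation each of these list calls was lost, at adjusted p = 0.924 for astrocyte, 0.929 for myelin, 0.796 for dentate gyrus, 0.771 for CA1, 0.796 for mitochondrially encoded genes and 0.796 for thalamus. Single Vehicle libraries stood apart. The dentate gyrus score was -0.584 in Vehicle 29 and from -0.086 to 0.018 in the other Vehicle libraries. The CA1 score was -0.81 in Vehicle 16 and from -0.289 to 0.148 in the others. In all, 274 genes were higher and 414 lower in Vehicle than in Basal (688 genes, edgeR), and 3024 passed at an unadjusted p under 0.05. The count was 346, 382 and 384 without Basal 14, 1 and 27, respectively, 355 with only the 2 groups in the fit, and 378 without Vehicle libraries 16 and 29. It was 1048 by limma-voom, 1070 with the sample number as a covariate and 1176 with 1 surrogate variable.

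Cort against Vehicle asks what added glucocorticoid changed in conditioned mice. Rbm24, an RNA-binding splicing regulator, was the gene that rose, from 16.1 ± 3.20 (SD, n = 4) to 25.5 ± 2.22 CPM (SD, n = 5), with a log2 fold change of 0.66 ± 0.11 (SE, adjusted p = 0.0159). The next smallest p-values, none of which passed, belonged to Spata2l (0.55 ± 0.10), Klf11 (-0.59 ± 0.12), Srl (0.65 ± 0.13) and Ippk (0.50 ± 0.10, SE, log2). DESeq2 called these 4 (adjusted p from 0.000715 to 0.0118), and in edgeR they passed with the sample number (highest adjusted p = 0.047) and without Vehicle 3 (0.0394) or Vehicle 23 (0.0237). Fkbp5 stood at 167 ± 9.89 CPM (SD, n = 5) against 130 ± 13 (SD, n = 4), and every Cort library lay above every Vehicle library, yet it did not pass (log2 0.36 ± 0.10 SE, edgeR adjusted p = 0.156), while DESeq2 called it (adjusted p = 0.0489). Arc (0.94 ± 0.35), Npas4 (1.01 ± 0.40) and Fos (0.87 ± 0.41, SE, log2) had higher means in Cort and did not pass. Of the receptor targets, 0 passed over all genes and 5 were higher adjusted over the list alone (median 0.12, camera adjusted p = 0.00757), and the call was lost, with adjusted p = 0.662 with an estimated correlation.

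The immediate early genes (5 of 40 higher adjusted over the list alone, median 0.22, adjusted p = 1.76e-06) and the dentate gyrus markers (8 higher and 1 lower of 17, median 0.28, adjusted p = 6.39e-07) were called by camera in Cort, with 0 of their members over all genes. Both calls were lost, with adjusted p = 0.472 with an estimated correlation. The dentate gyrus score was -0.584 in Vehicle 29 but -0.0078 in Vehicle 3, 0.018 in Vehicle 16 and -0.086 in Vehicle 23. Over all genes 1 was higher and 0 lower in edgeR, 1947 had an unadjusted p under 0.05, DESeq2 called 85 and limma-voom 1. The call of Rbm24 ended without Vehicle 29 (adjusted p = 0.0856), Cort 4 (0.0769) or Cort 30 (0.0626), and in edgeR it ended without Vehicle libraries 16 and 29 (0.67). Without Vehicle 23 the fit called 170 genes, and without Vehicle 3 it called 40. With the thalamus and neocortex scores as covariates it called 0, with 531 at an unadjusted p under 0.05. Without both Vehicle 16 and 29 it called 0, with 518.

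RU486 against Vehicle asks what blocking the receptor changed. The genes with the smallest p-values were Dbp, a circadian output transcription factor (39.8 ± 6.82 CPM, SD, n = 5, against 21.8 ± 2.26, SD, n = 4), Otof, Necab1, Cacna1g and Camk2d, and none passed (edgeR adjusted p from 0.0534 to 0.0563). DESeq2 called all 5 (adjusted p from 0.000398 to 0.00235), and in edgeR all 5 passed with the sample number or the choroid plexus score and without Vehicle 3 or Vehicle 23 (highest adjusted p = 0.0496, 0.0422, 0.0497 and 0.00448). Cdkn1a had 15.5 ± 4.46 CPM (SD, n = 5) against 44.4 ± 5.72 (SD, n = 4), a log2 fold change of -1.52 ± 0.29 (SE), and did not pass either (edgeR adjusted p = 0.0592), although DESeq2 called it (adjusted p = 0.00235). In edgeR it passed with the stricter filter (adjusted p = 0.0421), the sample number (0.0402), the choroid plexus score (0.0495) or without Vehicle 23 (0.0131). Of the 37 receptor targets, 0 passed over all genes and 15 were lower adjusted over the list alone, with a median of -0.21 (camera adjusted p = 3.63e-12). That call was lost, with adjusted p = 0.147 with an estimated correlation. Thalamus markers were lower beside them, 13 of 15 adjusted over the list alone (median -1.11, camera adjusted p = 8.83e-11, adjusted p = 0.191 with an estimated correlation). In edgeR 0 genes passed, 1366 had an unadjusted p under 0.05, DESeq2 called 45 and limma-voom 0. Without Vehicle 23 the fit called 207 genes, without Vehicle 3 it called 22 and without RU486 19 it called 1, and 6, 8 and 12 genes were called with the stricter filter, the sample number and the choroid plexus score. Vehicle 23 had the lowest thalamus and neocortex scores of the Vehicle libraries (-0.34 and -0.25). With the thalamus and neocortex scores as covariates the fit called 0 genes, with 496 at an unadjusted p under 0.05. Without both Vehicle 16 and 29 it called 0, with 362.

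C108 against Vehicle gave 9 genes higher and 27 lower (36 genes, edgeR). Among the largest falls were Vipr2, a receptor of vasoactive intestinal peptide (0.397 ± 0.0962 against 3.66 ± 5.16 CPM) and Foxp2, a transcription factor of deep cortical layers and thalamus (0.861 ± 0.117 against 4.68 ± 4.13 CPM, SD, n = 5 against 4). Rora, a nuclear receptor on the thalamus and clock lists, fell by 1.12 and Gria4, an AMPA receptor subunit, fell by 0.46 on the log2 scale. The rises were smaller, with Stac, an adaptor of calcium channels, at 0.94 ± 0.19, Bhlhe40, an activity-regulated repressor of the clock, at 0.62 ± 0.13, and Synpo, a protein of the dendritic spine apparatus, at 0.45 ± 0.10 (SE, log2). Fkbp5 was at 131 ± 12.8 CPM (SD, n = 5) and did not differ by the test (log2 0.01 ± 0.09 SE, edgeR adjusted p = 0.956).

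The spread of the falling genes lay in the Vehicle group, where markers of neighbouring regions differed between libraries. The thalamus score was 1.94 in Vehicle 16 and 1.07 in Vehicle 3 but -0.19 in Vehicle 29 and -0.34 in Vehicle 23, and the neocortex score was 0.71 in Vehicle 16 and 0.68 in Vehicle 29 but 0.055 in Vehicle 3 and -0.25 in Vehicle 23. In C108 the thalamus score was -0.51 ± 0.078 (SD, n = 5). Of 15 thalamus markers, 1 fell over all genes and 15 were lower adjusted over the list alone (median -1.52, camera adjusted p = 1.07e-10, adjusted p = 0.29 with an estimated correlation). For the neocortex markers 2 of 16 fell over all genes and 7 were lower adjusted over the list alone (median -0.39, adjusted p = 0.00283, adjusted p = 0.31 with an estimated correlation). Of the receptor targets, 0 passed over all genes and 1 was higher and 2 lower adjusted over the list alone (median -0.17, adjusted p = 0.00837), with adjusted p = 0.463 with an estimated correlation.

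The count against Vehicle changed with most of the libraries. It was 0 without Vehicle 16, C108 8, C108 34 or C108 39, 1 without C108 26 and 9 without Vehicle 29, but 656, 119 and 102 without Vehicle 23, Vehicle 3 and C108 21, respectively. It was 0 with only the 2 groups fitted, with the choroid plexus score, with 1 surrogate variable, with the thalamus and neocortex scores, or without Vehicle 16 and 29, was 7 with the sample number and 20 with no filter, and DESeq2 called 295 and limma-voom 248.

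**Figure D2:**
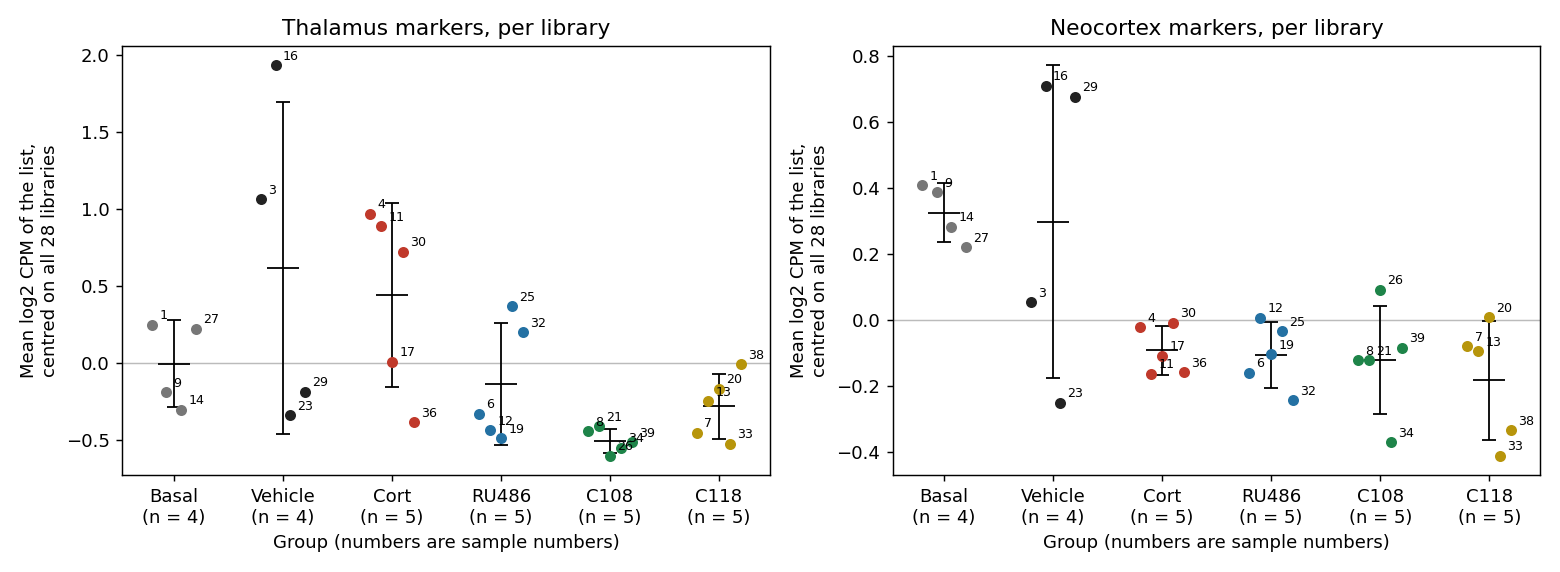
Scores of thalamus and neocortex markers (mean log2 CPM of the list, centred on all 28 libraries, vertical axes) in each library by group, with sample numbers and bars for the mean ± SD. Thalamus scores ran from -0.34 to 1.94 in Vehicle and from -0.61 to -0.41 in C108.

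C118 against Vehicle gave 0 genes in edgeR, with 1340 at an unadjusted p under 0.05, 45 by DESeq2 and 0 by limma-voom. The smallest p-values belonged to Efna5, an ephrin guidance ligand (2.52 ± 0.493 CPM, SD, n = 5, against 5.67 ± 2.34, SD, n = 4), Plxdc1, Necab1, Cacna1g and Camk2d, all with lower means in C118 and edgeR adjusted p from 0.0502 to 0.0687. DESeq2 called all 5 (adjusted p from 0.000918 to 0.00304), and in edgeR all 5 passed without Vehicle 23 (highest adjusted p = 0.000814). Cdkn1a had 20.6 ± 2 CPM (SD, n = 5) against 44.4 ± 5.72 (SD, n = 4) and did not pass (edgeR adjusted p = 0.201), but passed with only the 2 groups in the fit (edgeR adjusted p = 0.00124). Of the receptor targets 0 passed over all genes and 2 were lower adjusted over the list alone (median -0.20, camera adjusted p = 0.000359), with adjusted p = 0.537 with an estimated correlation. Thalamus markers were lower, 13 of 15 adjusted over the list alone (median -1.17, adjusted p = 1.64e-13, adjusted p = 0.14 with an estimated correlation). Without Vehicle 23 the fit called 214 genes and without Vehicle 3 it called 24, and 1, 1 and 2 genes were called with only the 2 groups, no filter and RLE normalization. With the thalamus and neocortex scores as covariates the fit called 0 genes, with 240 at an unadjusted p under 0.05. Without both Vehicle 16 and 29 it called 0, with 306.

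Interferon-stimulated genes, which are switched on in antiviral defence, had higher means in C118. For example, Ifit3b had 4.63 ± 3.13 CPM (SD, n = 5) against 1.91 ± 0.223 (SD, n = 4) in Vehicle and did not pass. Of 20 members, 0 passed over all genes and 8 were higher adjusted over the list alone (median 0.52, camera adjusted p = 3.4e-06), and the call was lost, with adjusted p = 0.537 with an estimated correlation. The score was 1.5 in C118 20 and 0.91 in C118 38, and at most 0.41 in the other 26 libraries. Without these 2 libraries the list no longer passed and its direction turned (adjusted p = 0.705).

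**Figure D3:**
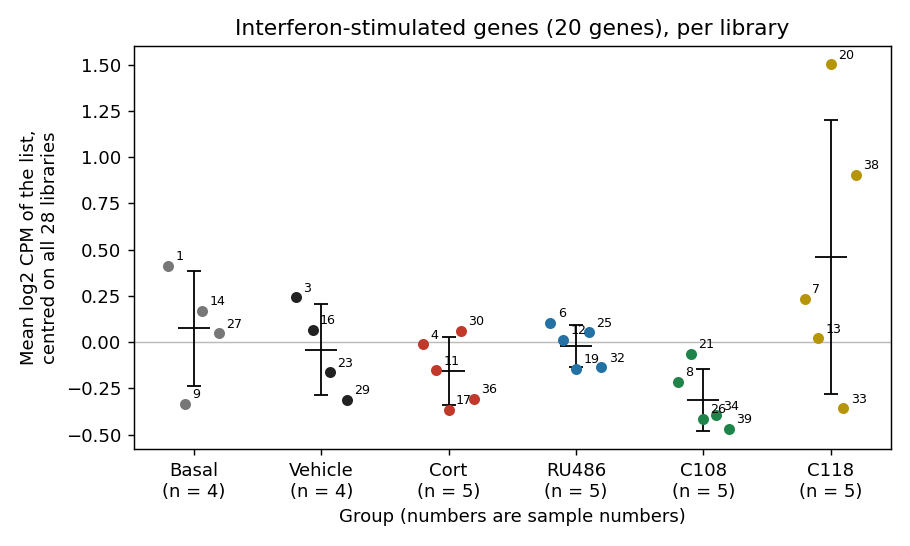
Score of 20 interferon-stimulated genes (mean log2 CPM, centred on all 28 libraries, vertical axis) in each library by group, with sample numbers and bars for the mean ± SD. C118 libraries 20 and 38 stand at 1.5 and 0.91, above the other 26 libraries.

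The direct comparison of Cort with RU486 sets receptor agonist against antagonist. Cort libraries had higher Cdkn1a (54.9 ± 15.2 against 15.5 ± 4.46 CPM, log2 1.83 ± 0.28 SE, edgeR adjusted p = 0.00557, n = 5 each) and higher Fkbp5 (167 ± 9.89 against 114 ± 8.28 CPM, log2 0.56 ± 0.09 SE, edgeR adjusted p = 0.00557, n = 5 each), and each passed on leaving out any of the 10 libraries. Also higher were Nrros, a regulator of microglial transforming growth factor signalling (0.86 ± 0.16), Pnpla2, a triglyceride lipase (0.73 ± 0.13), Dzip1l, a ciliary protein (0.54 ± 0.09), Aff1 (0.50 ± 0.10), Zbtb16, a zinc-finger transcription factor (0.50 ± 0.10), and Bcl2l1, an inhibitor of apoptosis (0.33 ± 0.06, SE, log2). Dbp was lower (-0.73 ± 0.14 SE, log2). Aff1 fell outside the rule for named genes and was chosen after its values were seen. Of the 37 receptor targets, 4 were higher over all genes and 17 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 8.65e-35), and the call held with an estimated correlation (adjusted p = 0.002). Beside them, camera called thalamus markers (median 0.66, adjusted p = 1.57e-07), meningeal and collagen genes (0.38, adjusted p = 0.00023) and myelin genes (-0.32, adjusted p = 1.17e-13). These 3 calls were lost, with adjusted p = 0.395, 0.595 and 0.395 with an estimated correlation. In all, 8 genes were higher and 1 lower in edgeR, 894 had an unadjusted p under 0.05, DESeq2 called 29 and limma-voom 36. The count was 3 without any of Cort 4, Cort 30, RU486 12, RU486 25 or RU486 32 and 3 with only the 2 groups fitted, where Cdkn1a did not pass (adjusted p = 0.0587). It was 21 with the sample number and 30 with 1 surrogate variable. Leaving out a library ended the calls of Pnpla2 in 6 of 10 cases (highest adjusted p = 0.139), Nrros in 6 (0.139), Zbtb16 in 8 (0.139), Bcl2l1 in 7 (0.269) and Dbp in 8 (0.216), with RU486 25 and RU486 32 among them for each.

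Cort against C108 and Cort against C118 compare the coded ligands with the agonist. Fkbp5 stood at 131 ± 12.8 CPM in C108 and 123 ± 15.9 in C118 against 167 ± 9.89 in Cort, and Cdkn1a at 24.9 ± 12.1 and 20.6 ± 2 against 54.9 ± 15.2 CPM (SD, n = 5 each), and none of the 4 differences passed over all genes in edgeR. By limma-voom, Cdkn1a and Fkbp5 passed against C108 (adjusted p = 0.00771 and 0.043) and against C118 (0.0454 and 0.0142). By DESeq2 both passed against C118 (adjusted p = 0.00621 each). In edgeR, Fkbp5 passed with 1 surrogate variable against C108 (adjusted p = 0.00445) and C118 (0.000604), and against C118 with the sample number (0.0296), with the choroid plexus score (0.0375) or without C118 38 (0.0316). Cdkn1a passed against C118 with only the 2 groups (edgeR adjusted p = 0.00736) or the sample number (0.0395). The receptor targets were lower in the coded ligands as a list. Against C108, 10 of 37 were higher in Cort adjusted over the list alone and 0 over all genes (median 0.21, camera adjusted p = 2.54e-17, adjusted p = 0.0416 with an estimated correlation). Against C118 the numbers were 5 adjusted over the list alone and 0 over all genes (median 0.25, camera adjusted p = 3.44e-19, adjusted p = 0.0463 with an estimated correlation). With fry neither passed (adjusted p = 0.0644 and 0.106). Against C118, thalamus markers were higher in Cort as well, 4 of 15 adjusted over the list alone and 0 over all genes (median 0.88, adjusted p = 0.119 with an estimated correlation), and meningeal and collagen genes had a median of 0.31 (camera adjusted p = 1.36e-05, adjusted p = 0.488 with an estimated correlation). Markers of other tissue moved with the targets against C108: 11 of 20 meningeal and collagen genes, 5 of 5 red blood cell genes and 7 of 15 thalamus markers were higher in Cort adjusted over the list alone, each with 0 over all genes and adjusted p = 0.0416 with an estimated correlation. Over all genes edgeR called 0 against C108 (817 at an unadjusted p under 0.05, DESeq2 5, limma-voom 24) and 0 against C118 (713, DESeq2 15, limma-voom 12). Against C118 the fit called 6 genes with the sample number, 3 with 1 surrogate variable, 1 with the choroid plexus score, 1 with only the 2 groups, 1 without Cort 11, and 3 without C118 33 or C118 38. Against C108 it called 1 with 1 surrogate variable.

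C108, C118 and RU486 did not differ in any gene over all genes. Against C118, C108 had lower interferon-stimulated genes, 13 of 20 adjusted over the list alone and 0 over all genes (median -1.17, camera adjusted p = 3.4e-26, adjusted p = 0.0468 with an estimated correlation), and fry did not call it (adjusted p = 0.213). Camera at the preset correlation still called the list without C118 libraries 20 and 38 (adjusted p = 0.00497), but an estimated correlation and fry were not tried there. The remaining scores were 0.234 in C118 7, 0.022 in C118 13 and -0.36 in C118 33. They overlapped those of C108, from -0.47 to -0.064. The smallest p-value belonged to Rtp4, an interferon-induced chaperone (0.825 ± 0.135 against 2.36 ± 1.44 CPM, SD, n = 5 each, edgeR adjusted p = 0.202), which passed by DESeq2 (adjusted p = 0.0229) and without C118 13 (0.0259) or C118 33 (0.0167). For C108 against C118 edgeR called 0 genes, 401 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and without C118 33 or C118 13 the fit called 8 and 1. Against RU486, edgeR, DESeq2 and limma-voom each called 0 genes for C108 and for C118, with 961 and 307 at an unadjusted p under 0.05. The unadjusted counts for C118 against RU486 and C108 against C118 lay below the share of 0.05 that chance alone gives. So did those for Cort against C108 and Cort against C118. The receptor targets had higher means than in RU486, with a median of 0.14 for C108 (camera adjusted p = 0.000165, 0 members over all genes and 0 adjusted over the list alone) and 0.11 for C118 (camera adjusted p = 8.68e-07, 0 and 0). These calls were lost, with adjusted p = 0.519 for C108 and adjusted p = 0.49 for C118 with an estimated correlation. Between C108 and C118 the list was not called (adjusted p = 0.746).

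The score of the receptor targets ordered the groups from Basal at -0.67 ± 0.20 (SD, n = 4) through RU486 at -0.089 ± 0.13, C108 at 0.037 ± 0.20, C118 at 0.052 ± 0.063 (SD, n = 5 each) and Vehicle at 0.23 ± 0.11 (SD, n = 4) to Cort at 0.35 ± 0.14 (SD, n = 5). Exact permutation tests were run for all 11 comparisons and adjusted over them. RU486 lay below Vehicle by -0.32 (95% interval -0.53 to -0.16, exact p = 0.00794, adjusted 0.0291) and C118 by -0.18 (-0.33 to -0.062, exact p = 0.0159, adjusted 0.0437). The list tests of these 2 comparisons were lost, with adjusted p = 0.147 and 0.537 with an estimated correlation and 0.14 and 0.469 by fry, and thalamus markers had lower means in both (medians -1.11 and -1.17). For C108 against Vehicle the difference was -0.20 (-0.43 to 0.10, exact p = 0.119, adjusted 0.164), and for Cort against Vehicle 0.12 (-0.085 to 0.30, exact p = 0.19, adjusted 0.233). Cort lay above RU486 by 0.44 (0.24 to 0.64, exact p = 0.00794, adjusted 0.0291), above C118 by 0.30 (0.13 to 0.45, exact p = 0.00794, adjusted 0.0291) and above C108 by 0.31 (0.037 to 0.59, exact p = 0.0317, adjusted 0.0499). Vehicle lay above Basal by 0.90 (0.50 to 1.22, exact p = 0.0286, adjusted 0.0499), with the smallest p that 4 against 4 libraries allow. C118 lay above RU486 by 0.14 (0.016 to 0.29, exact p = 0.0317, adjusted 0.0499), where the list test was lost, with adjusted p = 0.49 with an estimated correlation and 0.94 by fry, while C108 differed from RU486 by 0.13 (-0.12 to 0.39, exact p = 0.254, adjusted 0.279). C108 and C118 differed by -0.016, with an interval from -0.23 to 0.20 (exact p = 0.905).

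**Figure D4:**
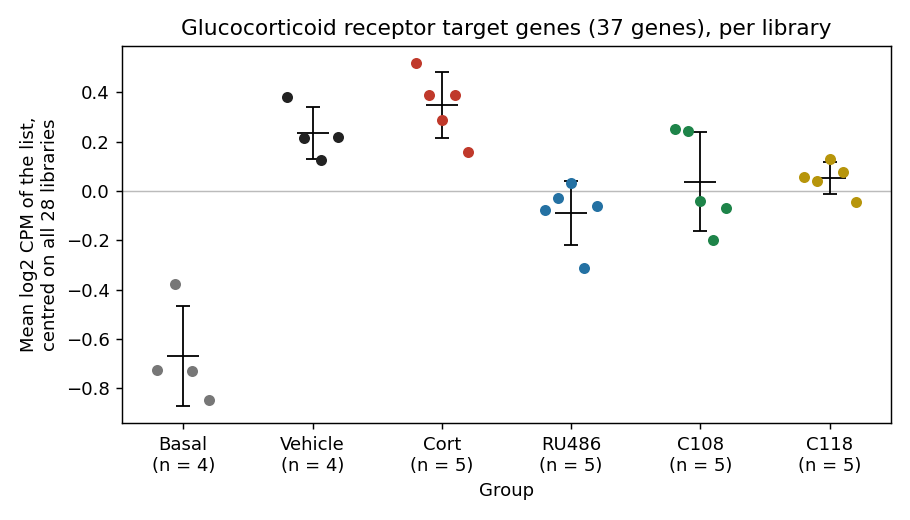
Score of 37 glucocorticoid receptor target genes (mean log2 CPM, centred on all 28 libraries, vertical axis) in each library by group, with bars for the mean ± SD. Every RU486 library lies below every Vehicle library and every Cort library, and every Basal library lies below every Vehicle library.

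The 4 ligand effects against Vehicle were compared across genes, which are not independent replicates. For C108 and C118 the covariance of the log2 fold changes was 0.0564. It was 0.0247 for simulated groups without any effect that share simulated Vehicle libraries, with genes drawn independently. The spread of the real Vehicle libraries gives an expected 0.0295 for every pair. Where the Vehicle libraries were divided 2 and 2 the covariance was 0.0271 on average. Ligands without effect have an expected covariance of 0 there only if nothing else separates the groups from Vehicle. The mean sample number was 17.75 in Vehicle, 18.8 in RU486, 19.6 in Cort, 22.2 in C118 and 25.6 in C108. Many genes followed that number within groups. For RU486 and C108 the observed, simulated and divided values were 0.046, 0.0245 and 0.0168, for Cort and C108 0.0451, 0.0246 and 0.0159, and for RU486 and C118 0.0396, 0.0247 and 0.0103. The values were 0.0367, 0.0248 and 0.00744 for Cort and C118, and 0.0333, 0.0247 and 0.00409 for Cort and RU486. Correlations across genes fell from between 0.634 and 0.773 with shared Vehicle libraries to between 0.0629 and 0.287 with divided ones. In 5 of the 6 pairs at least 1 division gave a negative covariance, and for C108 and C118 the divisions ran from 0.00718 to 0.0399. Among genes with at least 5 CPM the divided values fell to 0.0173 for C108 and C118 and to 0.0111 for RU486 and C108.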

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

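Tests of the C108 genes and of the interferon-stimulated genes were chosen after the results were seen. Among 120 groups of 4 or 5 libraries, 8 had a library far from the others, where chance alone gives 6. Sgk1 was 130 CPM in Basal 9 (next library 58.3) and Tsc22d3 63.2 CPM in the same library (next 42.1). Arc was 99.5 CPM in Vehicle 23 (next 63.3), and Npas4 was 5.84 CPM in Basal 14 (next 3.53) and 1.67 CPM in RU486 12 (next 5.22). C118 13 had 420 CPM of the choroid plexus transcript Ttr (next 50.6) and a choroid plexus score of 1.26 (next -0.77). RU486 6 had the lowest total of the RU486 libraries, 16.2 M counts (next in that group 19 M). No cause was tested for these libraries.

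Other results stood out as differences between ligands in a direct test. For Cort against RU486 these were the log2 fold changes of Cdkn1a (1.83), Nrros (0.856), Pnpla2 (0.734), Fkbp5 (0.555), Dzip1l (0.539), Aff1 (0.503), Zbtb16 (0.498), Bcl2l1 (0.326) and Dbp (-0.734). Lists that differed with an estimated correlation were the glucocorticoid receptor targets in Cort against RU486 (adjusted p = 0.002), Cort against C108 (0.0416) and Cort against C118 (0.0463), and the interferon-stimulated genes in C108 against C118 (0.0468). Meningeal and collagen genes (0.0416), red blood cell genes (0.0416) and thalamus markers (0.0416) also differed in Cort against C108.

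Other splits of the same libraries show which gene counts chance can give. For Vehicle against Basal 1 of 35 splits, the real one, gave as many genes, and the real count lay far above the rest (688, highest other 56). That is the smallest share that 35 splits allow, and it was not adjusted over the comparisons. Being first of 35 therefore does not exclude chance by itself. For C108 against Vehicle 4 of 100 splits, the real one included, gave as many (36, highest other 407). That share is small but was not adjusted over the comparisons, and the split with 407 genes lay far above the real one. It set Vehicle 23 with C108 21, 26, 34 and 39, which points to a structure of the samples. This measure therefore does not exclude chance for C108 against Vehicle. Chance cannot be excluded for Cort against Vehicle (12 of 100 splits, real 1, highest other 65) or for Cort against RU486 (6 of 100 splits, real 9, highest other 73). Where the real edgeR count was 0, 100 of 100 splits gave as many by construction, so the splits decide nothing. There the highest other count was 140 for RU486 against Vehicle, 106 for C118 against Vehicle, 2130 for C108 against C118, 0 for C108 against RU486, 1 for C118 against RU486, 325 for Cort against C108 and 1 for Cort against C118. The split with 2130 genes set C108 8 and 21 with C118 7, 13 and 20, all low sample numbers, which points to a structure that follows the sample number.

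Whether the genes that separated C108 from Vehicle reflect uneven tissue in the Vehicle libraries or an action of C108 was not decided. Their median change of 1.11 (log2, in each gene's direction, interquartile range 0.615 to 1.68) became 0.252 (0.148 to 0.452) against the mean of the other 3 ligands, with 0 genes called over all genes by edgeR. The genes were picked by their change against Vehicle in these same libraries, so a smaller change against other groups follows partly from that choice. With the thalamus and neocortex scores as covariates the median became 0.369 (0.293 to 0.6), although 3 of the 36 genes belong to those lists. Every C108 library had a lower thalamus score than every Vehicle library, so these covariates also remove a difference between the groups whatever its cause. The choroid plexus score left the median at 0.999. That choroid plexus explanation was set aside after its result was seen, and the covariate test was added after leaving out Vehicle 16 and 29 had decided nothing (0 genes and a median change of 0.538, 0.381 to 0.839, against a median of 48 genes, 0 to 1218, for the other 5 pairs). Against Basal the median was 0.321 (0.126 to 0.672), and single Vehicle libraries stood off from C108 by 1.61 (Vehicle 16), 0.912 (Vehicle 29), 0.723 (Vehicle 3) and 0.303 (Vehicle 23). A change from conditioning that all 4 ligands reverse stays open.

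The interferon-stimulated genes were high in C118 libraries 20 and 38, by 1.3 above the other 26 libraries. In C118 38 the microglia score lay -0.506 from the mean of the others and was the lowest of the 28 libraries, so more microglia were not seen there. Libraries with nearby sample numbers, Cort 36 (-0.428) and C108 39 (-0.479), had low microglia scores too. Of 21 microglia markers 5 fell and 0 rose with the sample number. The score cannot separate that trend from the amount of microglia in C118 38. More microglia in C118 20 stays open, since its microglia score was the highest of the 28 and lay 0.468 above that mean, against an interferon score of 1.5. The other 3 C118 libraries (0.234, 0.022 and -0.36) lay 0.00777 above the Vehicle mean (95% interval -0.538 to 0.554), so the high scores were not seen in every C118 library. C118 20 and 38 were picked as the highest, so lower scores in the other 3 follow partly from that choice. They do not decide whether C118 has an effect, and a smaller effect stays open. An immune response in single mice may remain as a hypothesis and was not tested.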

How the results depend on the processing

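Fits without Vehicle 16 and 29, fits without C118 20 and 38, and fits with the thalamus and neocortex scores were chosen after seeing the data. Counts of genes by setting follow. DESeq2 called 85 for Cort, 45 for RU486, 295 for C108 and 45 for C118 against Vehicle, 1 for C108 against C118, and 29, 5 and 15 for Cort against RU486, C108 and C118. limma-voom called 1048 for Vehicle against Basal, 248 for C108 against Vehicle, and 36, 24 and 12 for Cort against RU486, C108 and C118. With only the 2 groups in the fit the counts were 355 for Vehicle against Basal, 0, 0 and 1 for Cort, C108 and C118 against Vehicle, and 3 and 1 for Cort against RU486 and C118. With the sample number they were 1070 for Vehicle against Basal, 10, 8 and 7 for Cort, RU486 and C108 against Vehicle, and 21 and 6 for Cort against RU486 and C118. With 1 surrogate variable they were 1176 for Vehicle against Basal, 0 for C108 against Vehicle, and 30, 1 and 3 for Cort against RU486, C108 and C118. Without Vehicle 16 and 29 they were 378 for Vehicle against Basal and 0 and 0 for Cort and C108 against Vehicle. No filter gave 3, 1, 20 and 1 for Cort, RU486, C108 and C118 against Vehicle, and the stricter filter 2 and 6 for Cort and RU486. The thalamus and neocortex scores gave 0 and 0 for Cort and C108 against Vehicle, the choroid plexus score 12 and 0 for RU486 and C108 against Vehicle and 1 for Cort against C118, and RLE normalization 2 for C118 against Vehicle. The receptor target list had, with an estimated correlation, adjusted p = 0.662, 0.147, 0.463 and 0.537 for Cort, RU486, C108 and C118 against Vehicle, 0.519 for C108 and 0.49 for C118 against RU486. With fry these were 0.398, 0.14, 0.223, 0.469, 0.543 and 0.94, with 0.0644 and 0.106 for Cort against C108 and C118. For C108 against Vehicle the list had 0.102 with 1 surrogate variable and 0.125 with the thalamus and neocortex scores. Covariances with the Vehicle libraries divided 2 and 2 were 0.00409 (Cort and RU486), 0.0159 (Cort and C108), 0.00744 (Cort and C118), 0.0168 (RU486 and C108), 0.0103 (RU486 and C118) and 0.0271 (C108 and C118), and in the same order, with shared Vehicle libraries and at least 5 CPM, 0.0177, 0.0282, 0.0203, 0.0232, 0.0199 and 0.0295. Divided and with at least 5 CPM they were 0.00553, 0.016, 0.00815, 0.0111, 0.00774 and 0.0173. Directions turned for thalamus markers (0.619) and neocortex markers (0.714) in C108 against Vehicle with the thalamus and neocortex scores, which remove them by construction, for neocortex markers without Vehicle 16 and 29 (0.392), and for interferon-stimulated genes in C118 against Vehicle without C118 20 and 38 (0.705). Leaving out each library in turn gave 346 to 940 genes for Vehicle against Basal, 0 to 170, 0 to 207, 0 to 656 and 0 to 214 for Cort, RU486, C108 and C118 against Vehicle, 0 to 8 for C108 against C118, 3 to 9 for Cort against RU486, 0 to 3 for Cort against C118, and 0 to 0 for the other 3 comparisons. The highest counts against Vehicle came without Vehicle 23. Of the 199 results for named genes, those past the threshold kept their call in 487 and lost it in 239 tries of leaving out a library, and in 697 and 210 tries of the other alternatives. Those not past it gained a call in 45 and 84 tries, respectively. Apart from the scores that remove region markers by construction, the cause was not tested.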

Other observations

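The trend of genes with the sample number and the correlations with it were chosen as tests after the data were seen. Circadian clock genes were tested as a list. In Vehicle against Basal its members Arntl (edgeR adjusted p = 0.0111), Nr1d2 (0.0129), Rora (0.0202) and Cry2 (0.0259) passed over all genes. Leaving out a library ended these calls in 1, 3, 4 and 5 of 8 cases, respectively. In RU486 against Vehicle 5 of 21 were higher and 2 lower adjusted over the list alone, with 0 over all genes, camera gave an adjusted p of 0.00897 (adjusted p = 0.382 with an estimated correlation), and fry for movement in either direction gave 2.19e-05. Dbp, which drives daily rhythms of transcription, had 39.8 CPM in RU486 and 21.8 in Vehicle.

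Many genes followed the sample number in the titles, whose meaning the labels do not give. Within groups, 2102 genes rose and 2092 fell with the number (4194 genes, 25.1% of those tested), among them 17 of 23 endothelial markers that fell (median -0.26 on the log2 scale per 10 numbers, camera adjusted p = 3.07e-16, adjusted p = 0.243 with an estimated correlation). Of the 37 glucocorticoid receptor targets 1 rose and 6 fell with the number (median -0.068, camera adjusted p = 0.00588, adjusted p = 0.677 with an estimated correlation), the mean number per group ran from 12.75 in Basal to 25.6 in C108, and the tests of the target score do not adjust for it. Slc2a1, the glucose transporter of brain vessels, was at -0.28 and Psmc3, a proteasome subunit, at 0.15 per 10 numbers. With score and number centred on each group, over 28 libraries the endothelial score had a Pearson correlation of -0.8 with the number and a Spearman correlation of -0.817 (permutation p = 1e-05 for each, the smallest that 1e+05 permutations can give). Without the 2 farthest libraries the Pearson value was -0.789. The other of the 2 relations tested was the share of all counts in the HTSeq summary row __no_feature (Pearson -0.791, Spearman -0.82, permutation p = 1e-05 for each, -0.782 without the 2 farthest). That share leaves out the other summary rows that name no gene.

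For these genes 3 explanations were tested and none was decided. For time of day, 4 of 21 clock genes followed the number, where the share of all genes gives 5.3. The area under the curve between rising and falling genes was 0.593 for GC content and 0.377 for transcript length (SE 0.0089, with genes taken as independent). These values were short of the 0.8 or 0.2 set for a cause but not within 0.4 to 0.6 beyond the spread. The rules as first written did not ask for the spread. By them a clock gene share no larger than that of all genes spoke against time of day, and an area from 0.4 to 0.6 against GC content. Both values met those rules, but not beyond their spread, so both were left undecided. An order of dissection or library preparation may lie behind the number and was not tested.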
